A study of Mus musculus with 6 samples.

How the data were processed

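CUT&RUN libraries from sorted GFP-positive oocytes of Oct4-EGFP female embryos at E16.5 were grouped by antibody target from their titles, 2 each for H3K4me3, TAF4b and IgG. Per the labels' protocols, gonads were dissociated with trypsin, live cells were sorted on GFP against a non-transgenic baseline, and libraries were size selected by gel. The submitters' processing notes name bcl2fastq 2.20, Trim Galore 0.5.0, FastQC 0.11.5, Bowtie2 2.3.0, SAMtools 1.9, HOMER 4.10 and the build GRCm39, without the role or settings of each. Whether IgG served as the control in peak calling is not given in the sources used here. IgG was not analysed here.

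The authors deposited 1 annotated feature list for each TAF4b and H3K4me3 library, called per library and not pooled. Each feature has a peak score and a position per the file headers, which carry HOMER's column names. Except for 3 features each of TAF4b replicate 1 and H3K4me3 replicate 2, each also has an annotation class and a distance to the nearest TSS. This distance is signed and was read as measured from the feature centre, which the headers do not state. The scaling of the deposited score is not stated, so score levels were compared and tested only within a list. Uses across lists were the correlation of scores over shared TAF4b peaks, mean score percentiles, and the thinning of H3K4me3 replicate 1 scores. All scores (100%) fell on whole multiples of a step per list, within the rounding of the printed value plus 2% of the step. If a step stands for 1 tag scaled to a common total, which the sources do not state, the step of H3K4me3 replicate 2 was 3.06 times that of replicate 1, and the step of TAF4b replicate 2 was 2.64 times that of replicate 1. The TAF4b lists also hold a focus ratio, a fraction between 0 and 1 per the file headers, which was not used. Widths within the TAF4b lists were constant, and no H3K4me3 region was narrower than 500 bp. Such fixed widths affect every overlap.

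The columns for gene names were empty, and a table of RefSeq genes of the older build GRCm38.p6 matched 0 of the 9072 transcript identifiers, so no gene is named. For the same reason the planned tests of gene lists at TAF4b and at H3K4me3 promoters, and the gene-level tests of TAF4b against H3K4me3, could not be run. Without a genome sequence of the build, the planned motif test was not run either. The X chromosome test could not use all protein-coding genes as its background and used the other background set beforehand, promoter regions with H3K4me3, from which those with a TAF4b peak were removed. Coordinates are those of the files.

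A promoter feature was centred within 1 kb of a TSS. Features overlapped if they shared at least 1 bp. Shared TAF4b peaks were overlapping pairs of replicate 1 and replicate 2, described by their replicate 1 position. H3K4me3 regions of either list were those of replicate 1 plus those of replicate 2 that overlapped none of them. Overlaps were tested one-sided against 999 random placements of the features, each kept on its chromosome within the span of all listed features. Shares have exact (Clopper-Pearson) 95% intervals and were compared by two-sided Fisher's exact tests with conditional odds ratios. Differences in median were tested two-sided by permutation with 100000 resamples, with intervals from 2000 bootstrap resamples. The threshold was 0.05. Intervals cover counting error only, and the tests compare lists rather than conditions. Calculations used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and matplotlib 3.10.9 drew the plots.

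Regions are named by a rule fixed before the data were examined, as were the comparisons, except where the text says otherwise. The rule takes the 10 shared TAF4b promoter peaks with the highest mean score percentile, the 5 highest without H3K4me3, the 5 highest beyond 1 kb of a TSS and the 5 highest H3K4me3 regions in both lists, of which the text gives some. Its parts on gene lists and on Taf4b and Taf4 could not be applied without gene names. Features outside the rule are said to be chosen after their values were seen. The comparison of positions around the TSS, the H3K4me3 regions with and without TAF4b, the groups by score and the test of each chromosome were added after the lists were seen.

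The tests were tried on simulated data. With 200 overlapping peaks planted among 983 randomly placed TAF4b replicate 1 peaks, the placement test recovered a mean of 200.1 and passed the threshold in 20 of 20 runs, and with 0 planted it passed in 0 of 20. These runs used fewer placements than the main test. Both simulated lists ignored promoters, so the runs do not give the rate of false calls for lists that lie at promoters. For promoter shares of TAF4b replicate 1 against H3K4me3 replicate 1, Fisher's test passed in 9 of 200 runs with equal shares and in 200 of 200 with a planted difference of 30 percentage points. A shift of 2 in the median score of TAF4b replicate 1 peaks was recovered as 2.02 on average and passed in 40 of 40 runs, against 0 of 40 with no shift. The alternatives tried were other overlap rules, features at or above the median score of each list, placed chromosomes alone, other promoter windows, peaks of either TAF4b replicate, each replicate left out, and the replicate number as a block.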

Results

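TAF4b, a subunit of the general transcription factor TFIID, and H3K4me3, a histone mark found at active promoters, were mapped by CUT&RUN in mouse oocytes at E16.5, a stage of embryonic development. CUT&RUN directs a nuclease to an antibody target in isolated cells or nuclei and sequences the DNA it releases. The oocytes were GFP-positive cells sorted from female embryos carrying an Oct4-EGFP reporter, which marks germ cells, and were wild type for Taf4b. The 6 libraries comprised 2 each for H3K4me3, TAF4b and an IgG control. A list of called features was used for each of the 4 TAF4b and H3K4me3 libraries. IgG signal was not analysed here, so no background level stands beside the values. The design asks where TAF4b sits in the oocyte genome and how its sites relate to promoters that carry H3K4me3.

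TAF4b replicate 1 held 983 peaks of 90 bp and replicate 2 held 1111 peaks of 134 bp. H3K4me3 replicate 1 held 8129 regions of 500 to 3832 bp, which together covered 5438 kb of the GRCm39 genome. H3K4me3 replicate 2 held 320 regions of 500 to 2904 bp, covering 175 kb. The lists give no read totals, so the depth of each library is unknown. The authors' peak scores lie on whole multiples of a step that was 0.385 and 1.01 in TAF4b replicates 1 and 2, and 2.32 and 7.09 in H3K4me3 replicates 1 and 2. The lowest score of each list was 12, 11, 10 and 9 such steps, in the same order. The labels do not say whether the replicates came from separate animals. Features are not replicates, so each test below compares these lists, and its interval covers counting error only.

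TAF4b peaks lay almost entirely at promoters. Within 1 kb of a transcription start site (TSS) were 910 of the 983 peaks of replicate 1 (92.6%, exact 95% interval 90.8 to 94.1%). In replicate 2 the count was 1074 of 1111 (96.7%, 95.4 to 97.6%). The authors' annotation placed 89.9% and 95.1% of the peaks in its promoter class, 2.95% and 1.89% in introns, and 4.68% and 2.07% between genes. Peak centres within 100 bp of a TSS made up 59.7% of replicate 1 and 62.5% of replicate 2.

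H3K4me3 regions were spread more widely. In replicate 1, 4765 of 8129 regions lay within 1 kb of a TSS (58.6%, 57.5 to 59.7%). In replicate 2, 257 of 320 lay within 1 kb (80.3%, 75.5 to 84.5%). The annotation placed 43.8% and 69.1% of the regions of replicates 1 and 2 in its promoter class. The other classes of replicate 1 were introns with 30.1%, between genes with 14.1%, exons with 8.39% and transcription end sites with 3.63%. Regions centred within 100 bp of a TSS were 25.8% and 47.2% of the 2 lists. These regions are at least 500 bp wide, so one can cover a TSS and still be centred beyond 100 bp. Among the replicate 1 regions, the promoter share rose with the authors' score, from 48.0% in the lowest of 4 equal score groups to 72.6% in the highest.

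**Figure D1:**
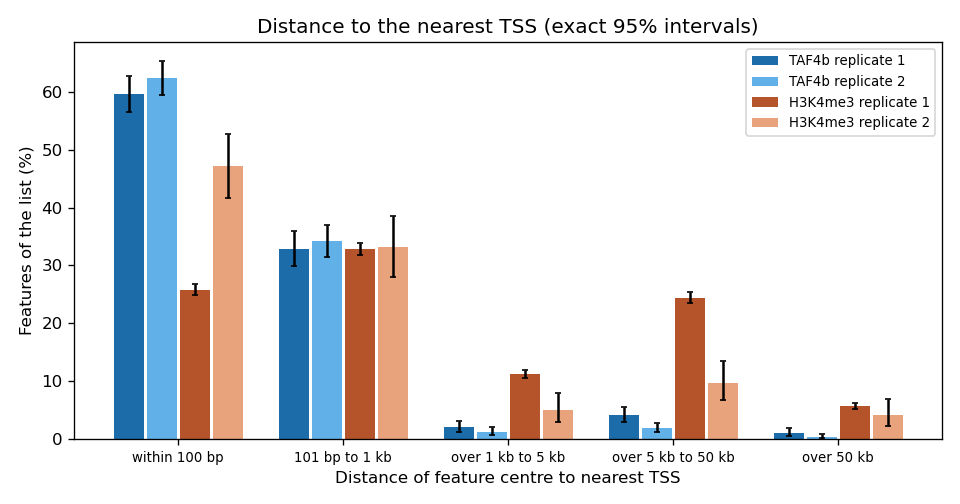
Bars give the percent of each list's features (y axis) in each class of distance from the feature centre to the nearest TSS (x axis), with exact 95% intervals as error bars. The TAF4b lists reach 59.7% and 62.5% within 100 bp, against 25.8% and 47.2% for H3K4me3. Widths differ between the targets, and a wide H3K4me3 region can cover a TSS and be centred further away.

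To compare the targets, the 429 TAF4b peaks present in both replicates were set against the 8218 H3K4me3 regions of either replicate. Of the shared TAF4b peaks, 421 lay within 1 kb of a TSS (98.1%, 96.4 to 99.2%), against 4819 of the H3K4me3 regions (58.6%, 57.6 to 59.7%). The odds ratio was 37.1 (95% interval 18.6 to 86.6, two-sided Fisher's exact test, p = 7.33e-82). The ratio was 20.5 without TAF4b replicate 1, 8.79 without TAF4b replicate 2, 12.9 without H3K4me3 replicate 1 and 4.52 with a window of 100 bp, each still past the threshold. The main sets are unlike, since TAF4b peaks had to be called in both replicates and H3K4me3 regions in either. They also differ in width. A wide region that covers a TSS can be centred outside the window, above all that of 100 bp, and this was not adjusted for. Of the 231 H3K4me3 replicate 1 regions also found in replicate 2, 204 lay within 1 kb of a TSS. The contrast is thus smaller between features shared by both replicates, and that form was not tested.

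The TAF4b replicates had 429 peaks in common by an overlap of at least 1 bp. These were 43.6% (40.5 to 46.8%) of replicate 1 and 38.6% (35.7 to 41.5%) of replicate 2. Centres of the shared peaks were a median of 27 bp apart. The overlap over both lists together was 41.0%, against a mean of 0.0102% when replicate 1 peaks were placed at random within their chromosomes (one-sided permutation p = 0.001, the smallest that 999 placements can give). Random placement ignores that both lists lie at promoters. Among the 4819 promoter regions with H3K4me3, 514 held a peak of replicate 1, 629 a peak of replicate 2 and 283 both, where independent lists would give 67.1. The odds ratio was 14.0 (11.3 to 17.3, two-sided Fisher's exact test, p = 2.72e-136), a test added after the lists had been seen. It treats these promoters as equally likely to hold a peak, though those with higher H3K4me3 scores held one more often. Unspecific signal at open promoters could raise it too, and IgG was not analysed here.

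Shared peaks were the stronger ones. In replicate 1 the median score was 9.24 for the shared peaks and 6.93 for the 554 others, a difference of 2.31 (bootstrap 95% interval 1.93 to 2.69). In replicate 2 the medians were 22.3 and 17.2 for the 429 shared and 682 other peaks, a difference of 5.1 (4.1 to 7.1). Both two-sided permutation tests gave p = 1e-05, the smallest that 100000 resamples can give. The share of replicate 1 peaks found in replicate 2 was 18.7% in the lowest of 4 equal score groups and 74.8% in the highest, and the share of replicate 2 peaks found in replicate 1 was 15.1% and 65.8%. Across the 429 shared peaks, which are not independent replicates, scores in the 2 libraries had a Spearman rho of 0.479 and a Pearson r of 0.477, each with a permutation p of 1e-05.

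**Figure D2:**
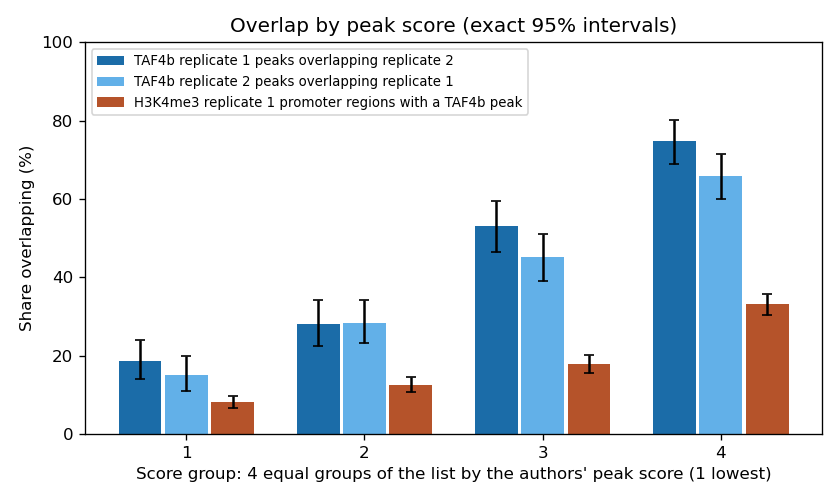
Bars give the percent of features that overlap the other list (y axis) in 4 equal groups of each list by the authors' peak score (x axis, 1 the lowest), with exact 95% intervals. In the lowest and the highest group the share is 18.7% and 74.8% for TAF4b replicate 1 peaks in replicate 2, 15.1% and 65.8% for TAF4b replicate 2 peaks in replicate 1, and 8.14% and 33.1% for H3K4me3 replicate 1 promoter regions with a TAF4b peak.

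The H3K4me3 replicates differed in the number of regions and in their promoter share. Of the 320 regions of replicate 2, 231 overlapped a region of replicate 1 (72.2%, 66.9 to 77.0%), against 0.55% at random placement (one-sided permutation p = 0.001, the smallest possible), which again ignores promoter position. Those 231 were 2.84% of the replicate 1 regions. Promoter regions of replicate 1 were found in replicate 2 in 4.28% of cases (3.72 to 4.90%), and regions beyond 1 kb in 0.803% (0.530 to 1.17%). Statements below on H3K4me3 rest chiefly on replicate 1.

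The strongest shared TAF4b promoter peaks were ranked by the mean of their score percentiles in the lists. The files give Ensembl transcripts without gene names, so these peaks are given by position on GRCm39 in replicate 1, with negative distances upstream of the TSS. The highest lay on chromosome 3 at 95532205 to 95532295, at -54 bp from the TSS of ENSMUST00000199421, with scores of 19.6 and 55.8 in replicates 1 and 2. It overlapped an H3K4me3 region of replicate 1. The next, on chromosome 14 at 67953251 to 67953341, lay at -6 bp from the TSS of ENSMUST00000150006, had scores of 21.2 and 47.7, and overlapped H3K4me3 regions of both replicates. The third, on chromosome 9 at 13738907 to 13738997, had scores of 18.9 and 53.8 and an H3K4me3 region in replicate 1.

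Most shared TAF4b peaks lay in H3K4me3 regions. Of the 429, 260 overlapped a region of either H3K4me3 list (60.6%, 55.8 to 65.3%), against 0.264% at random placement (one-sided permutation p = 0.001, the smallest possible). Random placement ignores that both targets lie at promoters, and no comparison with promoters as the background was made. Single lists gave like shares: 54.5% of TAF4b replicate 1 peaks and 58.1% of replicate 2 peaks lay in regions of H3K4me3 replicate 1. Peaks found in 1 TAF4b replicate lay in an H3K4me3 region in 280 of 554 cases (50.5%, 46.3 to 54.8%) for replicate 1 and 387 of 682 (56.7%, 52.9 to 60.5%) for replicate 2. Without H3K4me3 replicate 1 the share of the shared peaks was 6.76%, so the value depends on that list.

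The 169 shared TAF4b peaks outside H3K4me3 regions were also at promoters, 165 of them within 1 kb of a TSS. A region lay within 1 kb of 51 of the 169 (30.2%), while 105 (62.1%) had none within 10 kb. The strongest of them lay on chromosome 3 at 123302067 to 123302157, at -59 bp from the TSS of ENSMUST00000196466, with scores of 18.5 and 51.7 and the nearest region 121915 bp away. The next, on chromosome 14 at 20979267 to 20979357, lay at -154 bp from the TSS of ENSMUST00000226113 with scores of 19.6 and 45.7, and had a region 426 bp away. Peaks on chromosome 17 at 36152228 to 36152318, chromosome 7 at 45045258 to 45045348 and chromosome X at 150586129 to 150586219 followed, with the nearest region 4016, 149 and 301 bp away.

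TAF4b peak scores were not distinguishable with and without H3K4me3. The medians in replicate 1 were 8.08 for 540 peaks in a region and 7.7 for 443 outside (difference 0.38, bootstrap 95% interval 0 to 0.77, two-sided permutation p = 0.61). In replicate 2 they were 19.3 for 649 and 18.3 for 462 (difference 1, 0 to 2, permutation p = 0.505). Without H3K4me3 replicate 1, the difference in replicate 2 was 3 (1 to 7.1, permutation p = 0.025), over 67 peaks with a region.

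Seen from the mark, TAF4b was found at a minority of promoters with H3K4me3 and at few of its regions elsewhere. Of the 4765 promoter regions of H3K4me3 replicate 1, 853 held a TAF4b peak of either replicate (17.9%, 16.8 to 19%). Of its 3364 regions beyond 1 kb, 16 did (0.476%, 0.272 to 0.771%). This contrast follows from the promoter position of the TAF4b peaks and was not counted as a separate finding. Promoter regions with TAF4b had a median H3K4me3 score of 62.6, against 44.1 for the 3912 without (difference 18.5, 16.2 to 23.2). They were also wider, with medians of 760 and 500 bp (difference 260 bp, 106 to 276 bp). Both two-sided permutation tests gave p = 1e-05, the smallest possible. Over 4 equal groups of rising H3K4me3 score, the share of promoter regions with TAF4b was 8.14%, 12.6%, 17.8% and 33.1%. Wider regions have more room for an overlap, and this was not adjusted for.

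TAF4b peaks sat just upstream of the TSS. The median distance of promoter peaks was -58 bp in replicate 1 and -66 bp in replicate 2, and 80.3% and 83.8% of them were centred upstream. H3K4me3 promoter regions were centred at medians of 24 and 14 bp downstream, with 41.4% and 42.0% upstream. The 4 differences between a TAF4b and an H3K4me3 list were -82, -90, -72 and -80 bp, each with a two-sided permutation p of 1e-05, the smallest possible. The medians of the TAF4b replicates were 8 bp apart (bootstrap 95% interval 1 to 16 bp), which did not pass the threshold (two-sided permutation p = 0.0656). The offset was not distinguishable from 0 over transcripts that were nearest to both 1 shared TAF4b peak and 1 H3K4me3 region. Over these 125 transcripts the median offset was -14 bp (two-sided sign-flip permutation p = 0.649). For peaks of each TAF4b replicate against H3K4me3 replicate 1, the median of H3K4me3 minus TAF4b was 12 bp over 258 transcripts (bootstrap 95% interval -14 to 32 bp, two-sided exact sign test, p = 0.663) and 9 bp over 335 (-6 to 23 bp, p = 0.352 in the same exact test). Both intervals exclude the offset of 72 to 90 bp between the lists, for these matched transcripts alone. Features whose nearest transcripts differ, or that share a transcript with another feature of their list, drop out of the match. The match can thus favour close centres, so it cannot show that promoters with both targets lack an offset.

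**Figure D3:**
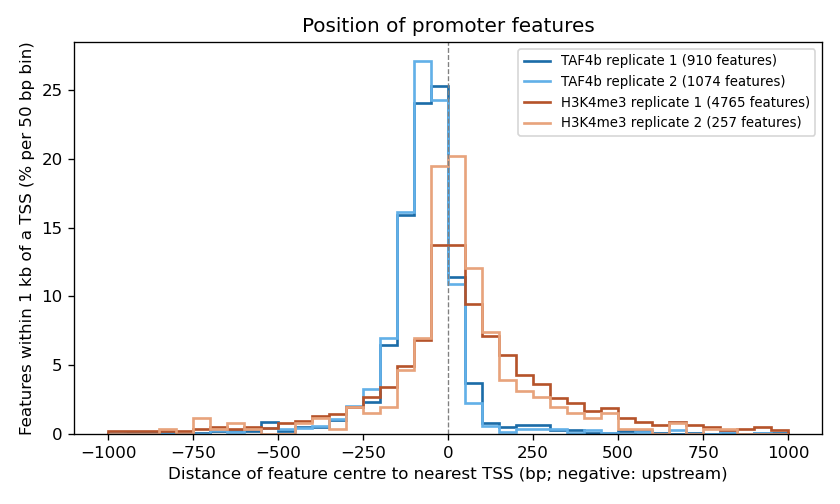
Lines give the percent of promoter features per 50 bp bin (y axis) by distance of the feature centre from the nearest TSS (x axis, negative upstream) for each of the 4 lists. TAF4b medians lie at -58 and -66 bp, and H3K4me3 medians at 24 and 14 bp.

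The X chromosome was examined because these are female germ cells. Of the 421 shared TAF4b promoter peaks, 8 were X-linked (1.9%), against 118 of 3960 H3K4me3 promoter regions without TAF4b (2.98%). The 421 include 165 outside any H3K4me3 region. This comparison, used for each chromosome, thus does not separate TAF4b from the mark. The odds ratio of 0.631 was not distinguishable from 1 (0.264 to 1.30, two-sided Fisher's exact test, p = 0.281). No chromosome of the 20 passed after Benjamini-Hochberg adjustment. Chromosome 10 came closest, with an odds ratio of 1.81 (1.18 to 2.70, Fisher's exact test, p = 0.00477, adjusted p = 0.0953).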

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

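Of 46 alternatives to 11 results, 39 were counted as planned before the data were examined. The other 7, those on TSS position and on overlap among promoters with H3K4me3, were chosen after seeing the data. Among the 39, the share of TAF4b peaks in same-numbered H3K4me3 regions replaced a planned gene-level form that could not be run. In 44 the direction and the side of the threshold were as reported, and 0 reversed. The exceptions were 2. Restricting the TSS position to promoters with the same nearest transcript gave a median offset of -14 bp, no longer past the threshold, against -95 bp between the lists; the cause of the smaller offset was not tested. For TAF4b scores with and without H3K4me3 in replicate 2, leaving out each H3K4me3 replicate gave differences of 1 to 3, and the value of 3, without replicate 1, passed the threshold; the cause was not tested. The share of shared TAF4b peaks in H3K4me3 regions ran from 6.76% without H3K4me3 replicate 1 to 61.5% with centres within 500 bp, and the promoter odds ratio from 4.52 with a window of 100 bp to 53.7 with the promoter annotation. Every alternative of a placement test stayed at the smallest possible p. Random placement ignores promoters and makes that outcome nearly certain, so an unchanged call there says little. The X chromosome odds ratio ran from 0.613 to 0.934 and did not pass in any of its alternatives. The labels do not say that a replicate number marks a shared animal or day, and with 2 pairs this could not be checked. With the replicate block, the promoter odds ratio was 8.55 and the share of TAF4b peaks in same-numbered H3K4me3 regions 28.8%, which changed no call. Not run were the settings on gene lists and motifs, the gene-level form of the replicate block, and reciprocal overlap for TAF4b in H3K4me3, which peak widths of 90 and 134 bp rule out. Unknown depth limits what absence from a list shows.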

Other observations

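The tests in this part were chosen after the lists had been seen, and of those on the short H3K4me3 list, the score percentile and the thinning had their predictions written before their results.

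H3K4me3 replicate 1 held 3364 regions beyond 1 kb of a TSS, 41.4% of the list. Of these, 1826 (54.3%) were annotated to introns, 604 of them (33.1%) to the first intron of a transcript, and 1144 (34.0%) lay between genes. Their median score was 39.4, against 46.4 at promoters, a difference that was not tested. A strong example found in both replicates lay on chromosome X at 95011010 to 95012482, at -11178 bp from the nearest TSS, with scores of 181 and 248.2. Of the 5 highest regions in both lists, 2 lay on an unplaced contig, among them the highest, with scores of 693.7 and 1148.6. The highest shared regions with a TAF4b peak lay on chromosome 1 at 131453842 to 131455790, with scores of 206.5 and 177.3, and on chromosome 13 at 92490864 to 92491795, with scores of 143.8 and 177.3.

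TAF4b peaks beyond 1 kb of a TSS were few, and in replicate 2 a larger share of them than of promoter peaks fell on the X chromosome. Counted on placed chromosomes, without unplaced contigs, 7 of 37 such peaks were X-linked (18.9%), against 26 of 1074 promoter peaks (2.42%), an odds ratio of 9.36 (3.18 to 24.5, two-sided Fisher's exact test, p = 5.77e-05, adjusted p = 0.000288 over 5 lists). In replicate 1 the difference did not pass, with counts of 4 of 68 (5.88%) and 20 of 910 (2.2%) and an odds ratio of 2.78 (0.670 to 8.64, Fisher's exact test, p = 0.079, adjusted p = 0.0987). The strongest of the 8 shared peaks beyond 1 kb lay on chromosome 15 at 101144268 to 101144358, with scores of 10.4 and 41.6. Of the 8, which are part of the replicate 2 list too, 2 were X-linked, at 65919947 to 65920037 and 169015770 to 169015860, between genes and at -37261 and -90541 bp from the nearest TSS (odds ratio 16.8, 1.45 to 116, Fisher's exact test, p = 0.0127, adjusted p = 0.0318). The X chromosome was chosen because X-linked peaks were seen among the named regions, which include these 8. The p-values of the TAF4b lists are therefore no independent support. The adjustment covers the 5 lists and not the choice of X among 20 chromosomes. In H3K4me3 replicate 1, the X-linked share was 2.77% of regions beyond 1 kb and 2.96% at promoters (odds ratio 0.933, 0.707 to 1.23, Fisher's exact test, p = 0.638). In H3K4me3 replicate 2 it was 5 of 58 (8.62%) and 7 of 256 (2.73%), with an odds ratio of 3.34 that did not pass (0.803 to 12.8, Fisher's exact test, p = 0.0505, adjusted p = 0.0841). Whether the X-linked share differed between TAF4b and H3K4me3 was not tested. No explanation was tested.

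The H3K4me3 list of replicate 2 is far shorter than that of replicate 1, 320 regions against 8129. Regions of replicate 1 also found in replicate 2 had a median score percentile of 81.2, which is consistent with a lower depth of replicate 2 keeping the stronger regions. Replicate 1 lacked 89 regions of replicate 2 (27.8%, 23.0 to 33.1%). These cannot decide whether lower depth was the whole cause, because each list has its own calling threshold. Scores of replicate 2 had a median of 12 steps and a lowest value of 9, so calls near the threshold may be among the 89. Among promoter regions of replicate 2, 54 of 257 were missing (21.0%, 16.2 to 26.5%). Replicate 1 also lacked 8 of the 10 with the highest scores. Some of those 8 lay on unplaced contigs, and whether they reflect the mark was not tested, so they carry little weight here. Thinning the scores of replicate 1 to the ratio of the steps left a mean of 2277 regions, though this assumes that 1 step is 1 tag and excludes nothing alone. Differences in antibody yield or background stay open, and no biological explanation was tested.

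Shared TAF4b peaks outside H3K4me3 regions were 169 of 429, nearly all at promoters. Peaks beside a region, missed by the overlap rule, may account for the 30.2% with a region within 1 kb. They cannot account for all, since 62.1% had no region within 10 kb. That the H3K4me3 lists are too short to hold every marked promoter stays open: 21.0% (16.2 to 26.5%) of the promoter regions of replicate 2 were missing from replicate 1, but whether the promoters in question carry the mark cannot be told apart from an incomplete list. No biological explanation was tested.

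Most TAF4b peaks, 554 of 983 and 682 of 1111, were called in 1 replicate. Their place near the calling threshold is a candidate explanation, since the shared percent rose 4.00 times from the lowest to the highest of 4 equal score groups in replicate 1, the smaller rise of the lists. Whether single-replicate peaks are unspecific stays open: they lay in H3K4me3 regions 0.834 times as often as shared peaks in replicate 1 (50.5% against 60.6%) and 0.929 times in replicate 2. Among promoter peaks the ratios were 0.915 and 0.952, not distinguishable from 1 (two-sided Fisher's exact tests, p = 0.122 and 0.341). Unspecific cuts at open promoters would lie there too, IgG was not analysed here, differences in depth or yield stay open, and no biological explanation was tested.

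A few features took outlying scores and were chosen after their values were seen. In H3K4me3 replicate 2, the region on chromosome 2 at 98496936 to 98497821 had a score of 27445.5, 39.7% of the summed score of that list, and was absent from replicate 1. Regions on chromosome 17 at 40154046 to 40156950 and chromosome 12 at 3159740 to 3160240 followed, with scores of 3956.2 and 2538.2. The highest TAF4b peak of replicate 2, on chromosome 17 at 40157876 to 40158010 with a score of 119.7, lay 926 bp from the first of these and was absent from TAF4b replicate 1. Of the 10 highest regions of H3K4me3 replicate 2, 2 lay within 1 kb of a TSS, against 7 of 10 in replicate 1. Regions on unplaced contigs were among the highest of both lists. IgG was not analysed here, so background cannot be told apart from the targets at these features. The nearness of the TAF4b peak and the H3K4me3 region on chromosome 17 is therefore no sign that the targets occur together.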
